A study of Mus musculus with 2 samples.

How the data were processed

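The data are from mouse tumour cells profiled on 1 lane of a droplet platform as a pool of 3 vehicle and 3 ACSS2i (ACSS2 inhibitor) samples, with an expression library and a protein library made from the same pool, per the labels. The labels state that 4000 to 6000 live cells of each sample were pooled. The deposited matrix holds counts of unique molecular identifiers (UMIs) for 31053 genes and 6 antibody tags (U2, U3, U4, D0, D1 and D4) in 9747 barcodes, and the values were used as raw counts. Cell Ranger and the mouse build mm10 are named per the submitters' processing notes, and the matrix was written by software version 3.1.0, per the file headers. The annotation the authors counted against is not given in the sources used here. Every barcode in the matrix held at least 500 gene UMIs.

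No label or file used here says which tag belongs to which arm. The 6 tags were therefore treated as 6 samples of unknown treatment, no arm was guessed from expression, and the planned comparison of ACSS2i with vehicle, with its tests of genes, shares and gene sets, was not run. Values per tag are given singly or as a range with a median, and only the closing section puts them to a test, for outlying samples.

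Barcodes were kept with at least 500 genes and under 15% mitochondrial UMIs. Below the gene minimum were 696 barcodes, and a further 267 were at or over the mitochondrial limit, which left 8784. Tags were assigned with HTODemux in Seurat 5.3.0 under R 4.3.3, with a positive quantile of 0.99 and seed 42. Cells positive for more than 1 tag numbered 865 (9.85%) and were removed as doublets. From the tag shares, 28.0% of doublets between tagged cells were estimated to join cells of the same tag, which tags cannot show. Doublets that include an untagged cell also show no more than 1 tag. They are not part of this estimate, so the share of doublets left in is larger and was not estimated. Scrublet was also tried, marked no cell of those passing the filters, and was not used. The 5590 cells with 1 tag (63.6%) and the 2329 with none (26.5%) were kept, 7919 in all.

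Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered with 15 neighbours and Leiden resolution 1.0 at seed 0 (scanpy 1.11.5, leidenalg 0.10.2, anndata 0.12.19). The clusters numbered 28. The marker lists, 23 in number, the 17 gene lists with 206 genes, the filters, the clustering settings and the rule for named genes were fixed before the data were examined. The rule took Acss2, Acss1 and Acly, the 6 members of each list with the most UMIs over all kept cells, and the 5 genes with the largest ratio of highest to lowest tagged sample among those averaging at least 50 UMIs per sample. Because that last part named no cell class, it was applied to Krt8-high cells. Genes outside the rule are marked where they appear as chosen after their values were seen.

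A cluster was named X-like when at least 3 markers of a list were 2-fold higher than in all other cells and seen in 20% of its cells, and when the mean log2 ratio over the list was at least 1. Clusters whose 10 leading genes held more markers of another class stayed unnamed. Clusters that no list named were joined as 1 population, called Krt8-high after its keratin 8 transcript, under 2 conditions. Their median cell had to reach 25% of the level of a signature of 33 genes (among them Sox9, Hmga2, Cxcl1 and Ereg). Their median UMIs also had to be not low against all cells. Fewer than 3 epithelial markers passed in any cluster of this population, so it was not called epithelial-like. A cluster of 196 cells at 46.1% of the signature level was kept out by its depth alone. Cells of a named cluster at 25% or more of that signature level were set aside as mixed, and they numbered 181. These naming thresholds, the signature and the mixed limit were set after the clusters had been seen and went through several versions, during which cluster names, signature levels and cell counts per class and tag were in view, and the class shares depend on them.

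UMIs were summed per class, or per class and tag, and given as CPM (UMIs relative to all gene UMIs of the class or sample, times 1000000). A gene is called higher or lower when the exact Poisson 95% intervals of its 2 CPM values do not overlap, and shares carry exact Clopper-Pearson 95% intervals. All intervals, and the limit of 3 counts used for a count of 0, cover counting error only. A tag and class entered a count over samples with at least 20 cells. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs. Free RNA was gauged by the signature level of each class as a percent of that in Krt8-high cells. The CPM that this percent would bring from Krt8-high cells was set beside some of the low values. The gauge takes all signature UMIs of a class as free RNA, so it can overstate it. Gene positions come from GENCODE M21 (GRCm38), in which 30934 of the 31053 gene identifiers were found. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 under Python 3.11.15.

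The interval rule was tested on simulated Poisson counts drawn from the Krt8-high profile at the total UMIs of each class. The test covered 7178 genes above a minimum level in Krt8-high cells, which left out Acss2 and Acss1. Coverage near the nominal level followed from the Poisson draw. Spread between cells and samples was not simulated, so the rates below cover counting error only. Between Krt8-high and T-like cells, 95.8% of intervals held the true CPM, 3.08% of unchanged genes had separate intervals, and so did 84.0% of genes set to 0.5 times their level and 96.0% of genes set to 2 times their level (50 genes each). For Krt8-high against macrophage-like cells, these were 96.0%, 3.10%, 96.0% and 100.0%. Alternatives for the filters, clustering, tag calls, doublets and naming were computed, and their effect is given in the closing section. A list of naive T cell genes was added after the data were seen, and a gene first placed on it was removed from it afterwards. Some results for single genes are not reported here.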

Results

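The data describe the cells of mouse tumours from a study titled for ACSS2 inhibitors in triple negative breast cancer, whose design text names Bmal1 status instead, a factor that no label of this pool gives. ACSS2 is the enzyme that turns acetate into acetyl-CoA in the cytosol and nucleus. Cells of 3 vehicle and 3 inhibitor-treated samples were pooled on 1 lane, and 1 expression matrix with 6 antibody tags was read. The pool held 9747 barcodes and 187339115 gene UMIs, with a median of 18388 UMIs, 3816 genes and 3.6% mitochondrial UMIs per barcode. Of 5590 cells with 1 tag, U2 held 2311, D1 1627, U3 614, D0 397, U4 392 and D4 249. Gene UMIs per tag ran from 4423414 (D4) to 50933086 (U2), and the median UMIs per cell from 1940 (U3) to 23062 (D1). Since the arm of each tag is not given in the sources used here, the comparisons below are between cell classes and among the 6 tagged samples. Some differences between classes carry counting intervals or the number of tagged samples that show them, and others are given as CPM or list ratios alone. Values given alone need not differ beyond their intervals or in every sample. No test over samples was run on differences between classes.

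Which cells made up the tumours was the question of the cell classes. Most cells belonged to a population with transcripts of the keratin genes Krt8 (780.3 CPM) and Krt18 (208 CPM), called Krt8-high here, which made up 5823 of 7919 cells (73.5%, 95% interval 72.5 to 74.5). T-like cells, named from T cell receptor genes such as Cd3e and Trbc2, were 9.72% (9.08 to 10.4, 770 cells), and macrophage-like cells, led by Lyz2, Apoe and the complement genes C1qa and C1qb, were 6.15% (5.63 to 6.70, 487 cells). NK-like cells (155, 1.96%) were led by the granzyme genes Gzmc and Gzmd, B-like cells (99, 1.25%) by Cd79a and Ms4a1, and dendritic-like cells (84, 1.06%) by class II genes and Ccr7. Fibroblast-like cells (60, 0.758%) and endothelial-like cells (35, 0.442%) were few. No cluster was named from the epithelial, pericyte, monocyte, neutrophil, plasma cell, erythroid, platelet, adipocyte, Schwann or muscle markers, nor from those of gamma delta T cells or of type 1 or plasmacytoid dendritic cells. That depends on the settings for neutrophils, since 78 neutrophil-like cells were named with a minimum of 200 genes, 14 with doublets kept and 9 without the cells tagged U3, and mast-like cells were named under the first 2 of these. A cluster of 29 cells with mast cell genes (Mcpt2, Cpa3) and neutrophil genes (S100a8, S100a9) and a cluster of 196 cells led by Gm42418, with 46.1% of the Krt8-high signature level and a median of 1358.5 UMIs, stayed unnamed (2.84% together, 0.860% to 3.32% per tag), and 181 cells were mixed (2.29%).

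The gene minimum sets part of these shares, because T-like cells had a median of 770 genes and Krt8-high cells 4427. With a minimum of 1000 genes the T-like share was 2.53% and the B-like share 0.179%, and with 200 genes the B-like share was 2.33%. Without the cells tagged U3, no cluster was named B-like. The dendritic-like share was 0.429% at Leiden 0.5 and 1.82% over tagged cells only, where the fibroblast-like share was 0.483% and the endothelial-like share 0.268%. The mixed share was 4.02% with mixed cells from 15% of the signature level and 1.14% from 50%, and the unnamed share ran from 0% (with a minimum of 1000 genes or doublets kept) to 4.50% (with a minimum of 200 genes).

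The tagged samples differed in their lymphoid cells. The T-like share was 41.0% (37.1 to 45.1) in U3 and lay between 8.91% (U2) and 16.1% (D0) in the other 5, whose order depends on staining, as given below. B-like cells were 14.3% (11.7 to 17.4) of U3 and 2.30% of U4, while U2 and D1 had 1 such cell each and D0 and D4 none, which allows shares of up to 0.756% and 1.20%. Macrophage-like cells made up 18.6% of D0, 13% of D1, 8.42% of U4, 5.84% of U2, 4.02% of D4 and 3.91% of U3. NK-like cells made up 9.07% (6.43 to 12.3) of D0 and 0.814% to 3.32% of the others. Krt8-high shares ran from 32.1% in U3 to 78.8% in U2, with intervals that do not overlap. Among immune cells alone, macrophage-like cells were 47.7% (43.0 to 52.5) in D1 and 6.22% (4.02 to 9.11) in U3. With a minimum of 1000 genes, the T-like share of U3 was 11.9%, its B-like share 3.13%, its Krt8-high share 61.25% and its macrophage-like share 10.6% (6.31 to 16.5), above those of U4, U2 and D4, so the gene minimum moves these values.

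**Figure D1:**
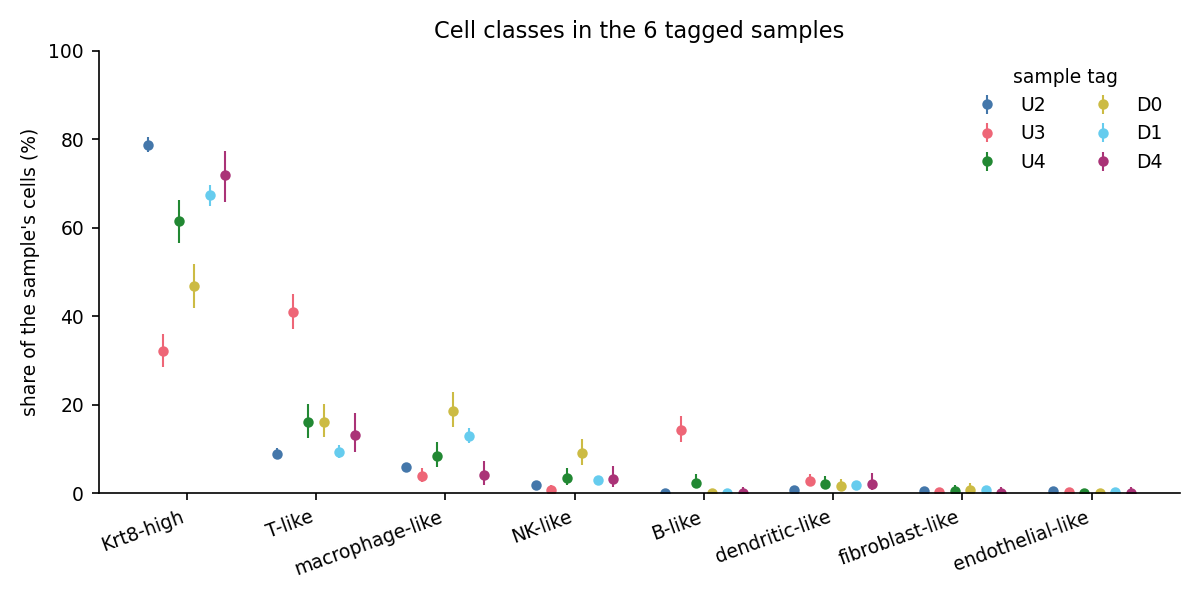
Share of cells (percent) in each cell class for the 6 tagged samples. T-like cells were 41.0% of U3 against 8.91% to 16.1% of the others, and Krt8-high cells ran from 32.1% (U3) to 78.8% (U2).

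Different T-like clusters filled different samples, which bears on any T-like value per tag. The cluster led by Satb1, Lef1 and the interleukin 7 receptor gene Il7r held 80.2% (74.7 to 84.9) of the T-like cells of U3 and 0% to 7.94% of those of the other 5. The cluster led by Nkg7 and Cd3g held most of those of U2 (79.6%), D4 (72.7%), U4 (65.1%) and D0 (60.9%), 45.4% of those of D1 and 11.9% of those of U3, and the cluster with regulatory T cell markers (Ctla4, Ikzf2, Tnfrsf4) held 51.3% of those of D1.

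Antibody staining differed by class. No tag was found on 36.1% (34.9 to 37.4) of Krt8-high cells, 56.7% (43.2 to 69.4) of fibroblast-like cells and 60.0% (42.1 to 76.1) of endothelial-like cells. Unnamed cells had the highest share, 157 of 225 (69.8%, 63.3 to 75.7), at a median of 1386 UMIs, near the 1541.5 of T-like cells. Among T-like cells 0 of 770 lacked a tag, which allows up to 0.390%, and 0 of 487 macrophage-like cells did, which allows up to 0.616%. Among NK-like cells, 1 of 155 lacked a tag. Krt8-high cells were 90.3% of all cells without a tag. Shares per tag therefore understate the Krt8-high cells: over tagged cells alone the Krt8-high share was 67.2% and the T-like share 13.9%. Untagged cells given to their strongest tag fell unevenly, with 625 added to the 392 tagged cells of U4 and 116 to the 2311 of U2. With them, T-like and B-like cells together were 36.5% of U3, 8.60% of D0, 8.53% of U2, 8.17% of D4, 7.08% of U4 (18.4% of its tagged cells) and 6.39% of D1, so the order of the shares among the 5 samples other than U3 changed.

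**Figure D2:**
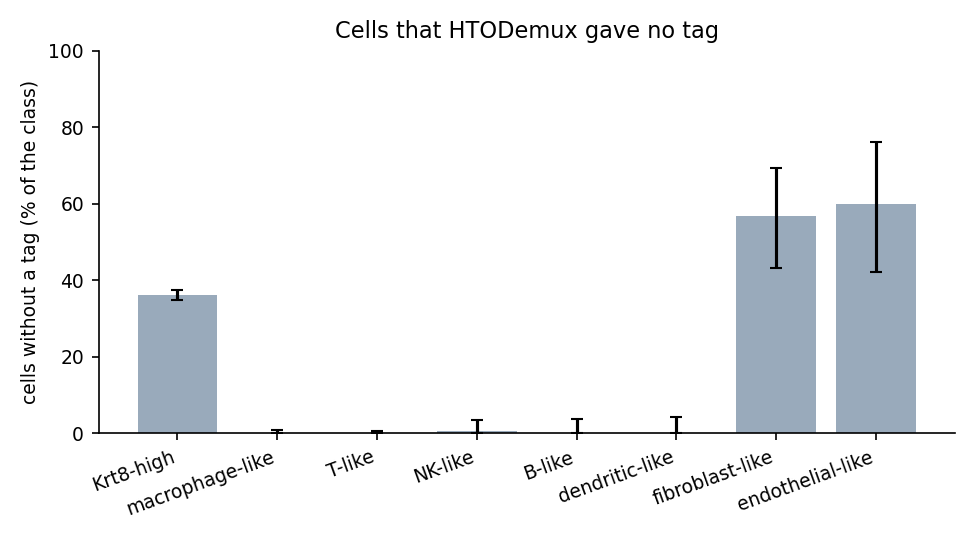
Share of cells (percent) without a tag in each cell class, with exact 95% intervals. Unnamed and mixed cells are not shown. It was 36.1% in Krt8-high cells and 0 of 770 in T-like cells.

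Where the acetate-using enzymes are transcribed was asked because ACSS2 is the drug target. Acss2 (ENSMUSG00000027605, chromosome 2, 155517948 to 155585724, plus strand, GRCm38, the whole gene span) was low in Krt8-high cells, at 2.0 CPM (1.78 to 2.24, 300 UMIs), and 8.14 times higher (5.08 to 12.4) in T-like cells, at 16.3 CPM (10.3 to 24.5, 23 UMIs). The T-like value was above that of the Krt8-high cells in 6 of 6 tagged samples, from 4.95 to 39.8 CPM with a median of 18.5, but these values rest on 1 to 6 UMIs each, and the intervals of the 2 classes were apart in 3 of the 6 (U3, U4 and D1). In macrophage-like cells Acss2 was 1.97 CPM (0.536 to 5.04, 4 UMIs), with an interval that overlaps that of the Krt8-high cells. NK-like cells held 3 Acss2 UMIs, a ratio to Krt8-high cells of 2.65 (0.543 to 7.81), and dendritic-like cells 3, a ratio of 5.11 (1.05 to 15.1). With a minimum of 1000 genes the T-like value of Acss2 was 7.44 CPM (2.03 to 19.0), which overlaps the Krt8-high interval. Across the tagged samples, Acss2 in Krt8-high cells ran from 1.60 to 3.04 CPM with a median of 1.98.

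Acss1 (ENSMUSG00000027452, chromosome 2, 150618105 to 150668500, minus strand, GRCm38), the mitochondrial enzyme for the same reaction, had 0 UMIs among the 149823271 of the Krt8-high cells, which allows up to 0.0200 CPM. In macrophage-like cells Acss1 was 8.85 CPM (5.25 to 14.0, 18 UMIs) and in T-like cells 8.50 CPM (4.39 to 14.9, 12 UMIs). These point values were 442 and 425 times the limit for all Krt8-high cells together. The ratios leave out the counting error of the 18 and 12 UMIs. Dendritic-like cells held 5 Acss1 UMIs (17.1 CPM, 5.54 to 39.8). Acss1 was above 0 in 4 of 5 tagged samples in macrophage-like cells and in 4 of 6 in T-like cells. Acly (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000, minus strand, GRCm38), which makes acetyl-CoA from citrate, was more even: 43.6 CPM (42.6 to 44.7) in Krt8-high cells, 64.4 (53.9 to 76.5) in macrophage-like cells, 1.48 times higher (1.23 to 1.76) and higher in 4 of 5 samples, and 39.0 (29.4 to 50.7) in T-like cells, with overlapping intervals.

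At equal depth Acss2 kept its order. In cells thinned to 1000 UMIs, it was seen in 1.71% (0.885 to 2.96) of T-like and 0.224% (0.119 to 0.382) of Krt8-high cells, while the unthinned shares were 2.73% and 4.64% at median depths of 1541.5 and 24101 UMIs. Acss1 was seen in 0.996% (0.401 to 2.04) of thinned T-like cells (1.56% unthinned) and 0.417% (0.0505 to 1.5) of thinned macrophage-like cells (3.49% unthinned, median depth 3698), and in 0 of 5812 thinned Krt8-high cells, which allows up to 0.0516%, so the macrophage-like difference was not detectable in thinned cells. Acly was seen in 4.18% of thinned Krt8-high, 6.67% of macrophage-like and 3.84% of T-like cells (57.1%, 22.6% and 6.62% unthinned). As a gauge of free RNA, Krt8 was seen in 44.9% of thinned Krt8-high cells and in 5.26% of T-like cells, which should lack it (97.3% and 8.44% unthinned), and Cd3e in 39.3% of thinned T-like and 0 of 5812 Krt8-high cells (57.8% and 0.292% unthinned). The depth left out 11 Krt8-high, 7 macrophage-like and 67 T-like cells.

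**Figure D3:**
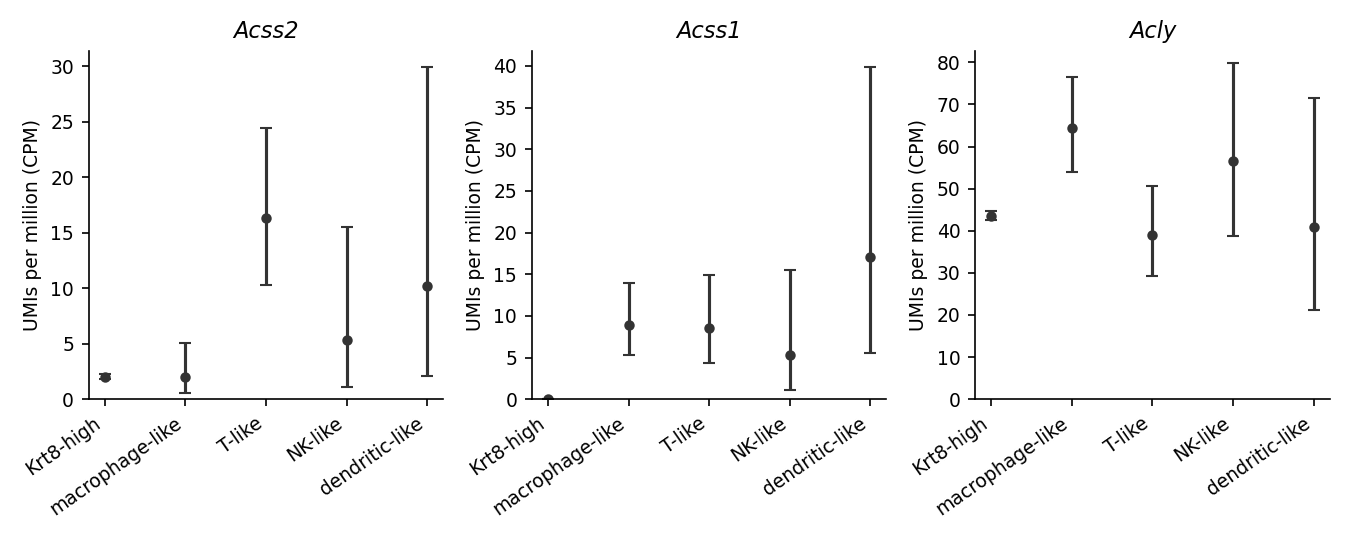
CPM of Acss2, Acss1 and Acly per cell class, with exact 95% intervals. Acss2 was 16.3 CPM in T-like and 2.0 in Krt8-high cells, and Acss1 had 0 UMIs in Krt8-high cells.

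Of the 22 genes of acetate and acetyl-CoA handling, 7 were higher, 6 lower and 9 overlapping in macrophage-like against Krt8-high cells, and 6, 6 and 10 in T-like cells. Pdha1 (a subunit of pyruvate dehydrogenase) was 79.3 CPM in Krt8-high, 55.1 in macrophage-like and 58.8 in T-like cells, and the histone deacetylase gene Hdac2 71.2, 26.6 and 39.0. The acetyltransferase gene Ep300 went the other way, with 51.9 in Krt8-high, 69.8 in macrophage-like and 74.4 in T-like cells. Crebbp (70.1, 82.1 and 87.2 CPM) and Acat1 (40.8, 47.7 and 39.7 CPM) are named by the same rule. The monocarboxylate transporter genes, chosen after their values were seen, parted by class: Slc16a1 was 36.8 CPM in Krt8-high and 8.36 in macrophage-like cells, and Slc16a3 was 0.147 and 187. The list as a whole was 1.28 times the Krt8-high level in macrophage-like cells (higher in 5 of 5 samples) and 0.981 times in T-like cells (higher in 3 of 6). The macrophage-like excess was no larger than Slc16a3 alone, since the list was 734 CPM there, 187 of it from that gene, and 574 in Krt8-high cells.

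Lipid synthesis genes were lower in the immune classes. Of 10 fatty acid synthesis genes, 8 were lower and none higher in macrophage-like cells, and 8 lower and 1 (Elovl5) higher in T-like cells; the summed list was 0.301 times and 0.317 times the Krt8-high level, lower in all 5 and all 6 samples. The desaturase genes Scd1 and Scd2 were 118 and 281 CPM in Krt8-high cells, 11.8 and 79.2 in macrophage-like cells, and 9.21 and 62.4 in T-like cells. Me1, the malic enzyme that supplies NADPH, was 77.1 CPM in Krt8-high and 4.92 in macrophage-like cells, where free RNA from Krt8-high cells alone would give 4.81. Of 17 cholesterol synthesis genes, 12 were lower in macrophage-like and 14 in T-like cells, and none was higher. Hmgcs1, an early enzyme of that path, was 242, 60.5 and 43.9 CPM in Krt8-high, macrophage-like and T-like cells, and Sqle (squalene epoxidase) 152, 24.1 and 20.6. The cholesterol list was 0.424 times and 0.328 times the Krt8-high level, lower in every sample compared.

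Fatty acid oxidation was split, with 3 of 10 genes higher and 2 lower in macrophage-like cells and 2 higher and 1 lower in T-like cells. Hadhb, a subunit of the mitochondrial trifunctional protein, was 21.2, 47.2 and 56.7 CPM in Krt8-high, macrophage-like and T-like cells, and Acadm, an acyl-CoA dehydrogenase, 48.0, 55.6 and 24.8. The list ratios were 1.06 and 1.04. Of 14 glycolysis genes, 8 were lower and 3 higher in macrophage-like cells (list ratio 0.709) and 13 were lower and 1 higher in T-like cells (0.445), lower in every sample compared. Pgam1 was 1379, 819 and 286 CPM, Pkm (pyruvate kinase) 1510, 919 and 605, and Ldha (lactate dehydrogenase) 1172, 867 and 638 in Krt8-high, macrophage-like and T-like cells. Of 10 hypoxia genes, macrophage-like cells had 4 higher and 4 lower (list ratio 1.04) and T-like cells 1 higher and 8 lower (0.346). Vegfa, the endothelial growth factor gene, was 278, 557 and 28.3 CPM, while Ndrg1 was 292, 72.8 and 53.1 and the carbonic anhydrase gene Car9 was 108, 11.8 and 7.80.

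Interferon and antigen presentation genes differed between the immune classes. Of 11 type I interferon genes, 9 were higher and 2 lower in macrophage-like cells (list ratio 2.28, higher in 5 of 5 samples), and 7 higher and 2 lower in T-like cells (1.91, 6 of 6); NK-like cells had 6 higher and 3 lower (1.37, higher in 1 of 3 samples), dendritic-like cells 5 and 3 (1.66, and 1.57 in the 1 sample compared) and B-like cells 2 and 3 (0.571, and 0.62 in the 1 sample compared). Isg15, which encodes a ubiquitin-like protein induced by interferon, was 172, 329 and 291 CPM in Krt8-high, macrophage-like and T-like cells, and Rsad2 was 40.5, 207 and 69.4. Of 11 interferon gamma genes, 6 were higher and 2 lower in macrophage-like cells (1.5, 4 of 5), and 5 higher and 4 lower in T-like cells. The other immune classes had more of these genes lower than higher: 3 were higher and 5 lower in NK-like cells (0.647, lower in 3 of 3 samples), 4 and 6 in dendritic-like cells (0.898, and 0.649 in the 1 sample compared) and 1 and 4 in B-like cells (0.238, and 0.690 in the 1 sample compared). Of the 99 B-like cells 88 were tagged U3, where the Krt8-high level of this list was lowest, so the pooled B-like ratios also carry a difference between samples. The chemokine gene Cxcl10 was 201, 480 and 237 CPM in Krt8-high, macrophage-like and T-like cells and the GTPase gene Iigp1 212, 66.4 and 62.4. Of 10 MHC class I genes, 7 were higher in macrophage-like and 8 in T-like cells, with list ratios of 1.17 (higher in 2 of 5 samples) and 1.57 (6 of 6), 8 in NK-like (1.34, 2 of 3) and in dendritic-like cells (1.46, 1 of 1), and 3 in B-like cells (0.798, though 1.07 in the 1 sample compared). H2-K1, whose reads can be shared with other class I genes, was 872, 1545 and 2741 CPM, and the immunoproteasome gene Psmb8 139, 445 and 746. All 7 MHC class II genes were higher in macrophage-like cells, with a list ratio of 747. Cd74, the class II invariant chain, was 6.17 CPM in Krt8-high, 5857 in macrophage-like and 137 in T-like cells.

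Cytotoxic effector genes were higher in T-like and NK-like cells, and checkpoint genes in several immune classes. All 13 cytotoxic effector genes were higher in T-like cells (list ratio 38.6, higher in 6 of 6 samples), and 11 of 13 were higher in NK-like cells (75.4, 3 of 3). Gzmb (granzyme B) was 0.541 CPM in Krt8-high and 740 in T-like cells, Nkg7 0.587 and 1003, and Ccl5 132 and 2068. In macrophage-like cells 6 of the 13 were higher, with a pooled list ratio of 2.62, a median of 1.37 over samples, and a higher list in 4 of 5. In dendritic-like cells 3 were higher (35.5) and in B-like cells 1 (6.12). All 10 checkpoint genes were higher in T-like cells (192 times, 6 of 6 samples) and 6 of 10 in macrophage-like cells (64.6 times, 5 of 5), 9 in NK-like cells (71.0 times, 3 of 3), 8 in dendritic-like cells (69.7 times) and 4 in B-like cells (22.0 times). Ctla4 and Pdcd1, inhibitory receptors of T cells, were 384 and 162 CPM in T-like cells and 0.10 and 0.0734 in Krt8-high cells, and Entpd1 was 99.9 in macrophage-like and 43.9 in T-like cells.

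The suppressive myeloid list parted from its name. In macrophage-like cells 8 of 11 genes were higher, among them Arg1 (1555 CPM against 0.461), Il1b (3127 against 1.31) and Cxcl2 (2550 against 54.3), yet the summed list was 0.325 times the Krt8-high level. Spp1 (osteopontin) made that sum: it was 31351 CPM in Krt8-high cells and 1965 in macrophage-like cells, where free RNA from Krt8-high cells alone would give 1956. That gauge can overstate free RNA, since in endothelial-like cells the summed list was 608 CPM against 2110 expected from it. How much of the macrophage-like Spp1 was free RNA is therefore not settled. In T-like cells 4 of the 11 genes were higher and 5 lower, with Spp1 at 1551 CPM, and the list ratio was 0.0573.

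Of 12 cell cycle genes, macrophage-like cells had 1 higher and 6 lower (list ratio 0.614, lower in 5 of 5 samples) and T-like cells 4 higher and 3 lower. Cdk1 was 145, 42.8 and 43.9 CPM and the proliferation marker Mki67 83.4, 93.5 and 178 in Krt8-high, macrophage-like and T-like cells. Cdk1 belongs to the signature that joined the Krt8-high clusters, whose genes were picked as higher there, so its gap followed from that choice. It counts among the lower genes of both classes. Of 16 circadian clock genes, 8 were lower and 1 higher in macrophage-like cells (0.629, lower in 5 of 5 samples), and 6 lower and 5 higher in T-like cells. The clock repressor gene Nr1d1 was 60.4, 4.43 and 0.709 CPM (9 UMIs in macrophage-like and 1 in T-like cells), and Bhlhe40 was 284, 203 and 420. Of 12 dissociation stress genes, 6 were higher and 6 lower in macrophage-like cells (0.853) and 2 higher and 8 lower in T-like cells (0.421). Fos was 2218, 1987 and 245 CPM in these classes and Egr1 651, 130 and 51.0. Of 10 genes of the epithelial to mesenchymal list, 9 were lower in macrophage-like and 8 in T-like cells (0.394 and 0.195). Vim (vimentin) was 6824, 2795 and 1710 CPM, and Sparc 1808, 55.6 and 119, where free RNA would give 113 in macrophage-like and 98.3 in T-like cells; Zeb2 was higher in macrophage-like cells (593 against 94.9).

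In T-like cells the interferon gamma, cell cycle and circadian clock lists had pooled ratios to Krt8-high cells of 0.933, 0.935 and 0.917, while within samples they were higher in T-like cells in 4, 4 and 3 of 6, with median ratios of 1.29, 1.14 and 1.01. Their direction turns with the settings: without the cells tagged U3, the interferon gamma, cell cycle and circadian clock lists in T-like cells were higher than in Krt8-high cells, by 0.13, 0.20 and 0.15 on the log2 scale, and the cell cycle list by 1.05 with a minimum of 1000 genes.

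**Figure D4:**
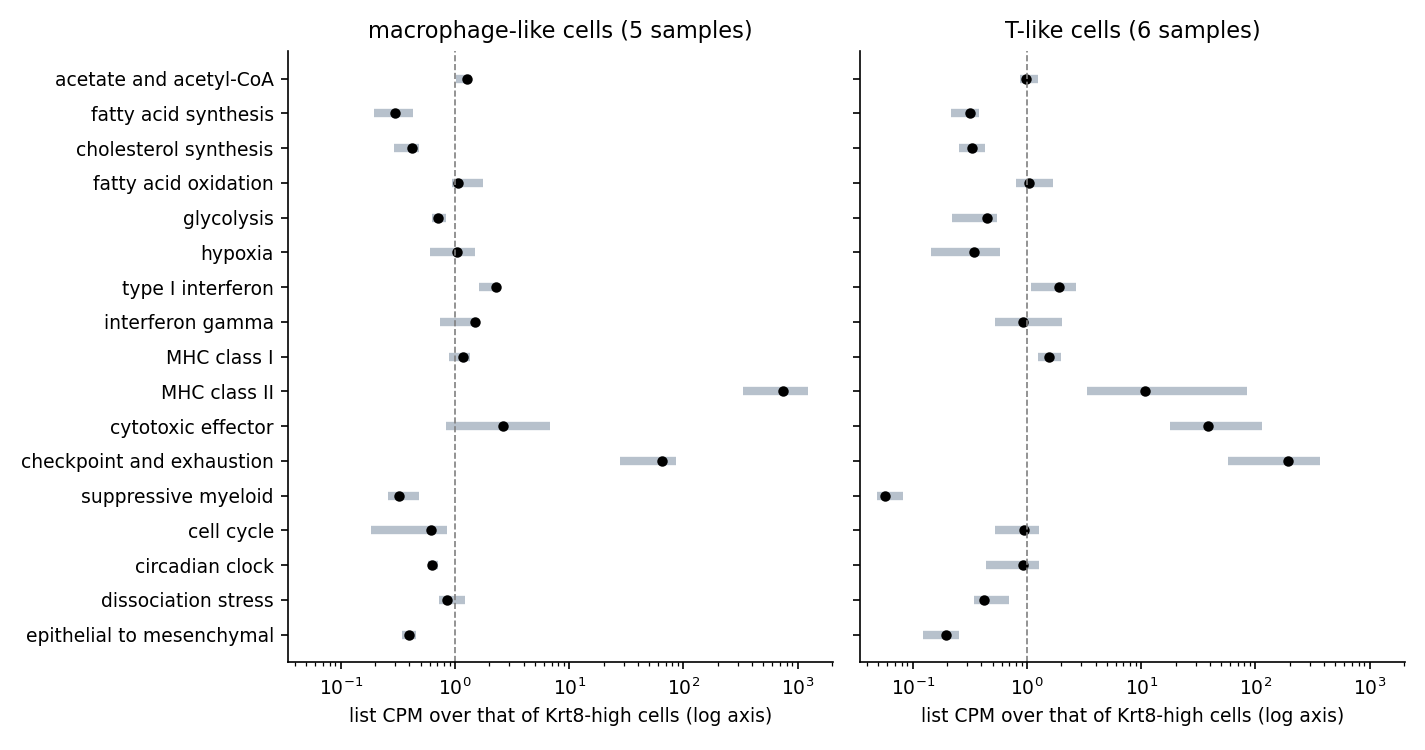
Ratio of each summed gene list to the Krt8-high level in macrophage-like and T-like cells, on a log axis; points are pooled cells and bars run from the lowest to the highest tagged sample. The cholesterol list was 0.424 and 0.328 times the Krt8-high level, and the MHC class II list 747 and 10.7 times.

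Among the 6 tagged samples, the 17 lists in Krt8-high cells had ratios of highest to lowest sample from 1.05 (acetate) to 8.0 (MHC class II). The interferon gamma list was 1480 CPM (1469 to 1491) in U2, 926 in D0, 882 in D4, 784 in D1, 611 in U4 and 372 (355 to 390) in U3, a ratio of highest to lowest of 3.98. Without U3 that ratio was 2.42. The MHC class I list ran in the same samples from 4430 CPM (U3) to 8002 (U2), a ratio of 1.81, and the MHC class II list from 4.78 (D4) to 38.2 (U2), a ratio of 8.0 that was 17.2 with a minimum of 1000 genes. The type I interferon list had another order, with 1272 CPM in D0 and 524 to 745 in the others, a ratio of 2.43. The acetate list differed by 1.05 times between the highest and the lowest sample, fatty acid synthesis by 1.06, fatty acid oxidation by 1.06, the epithelial to mesenchymal list by 1.1, glycolysis by 1.14, the clock list by 1.18, cholesterol synthesis by 1.37, hypoxia by 1.39, the suppressive myeloid list by 1.48, the cell cycle by 1.57 and dissociation stress by 1.73. The cytotoxic list ran from 51.8 (U4) to 348 CPM (D0), a ratio of 6.71, nearly all of it from Ccl5 (47.4 and 343 CPM in those samples), and the checkpoint list from 2.29 (U4) to 6.54 (D0), a ratio of 2.86.

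**Figure D5:**
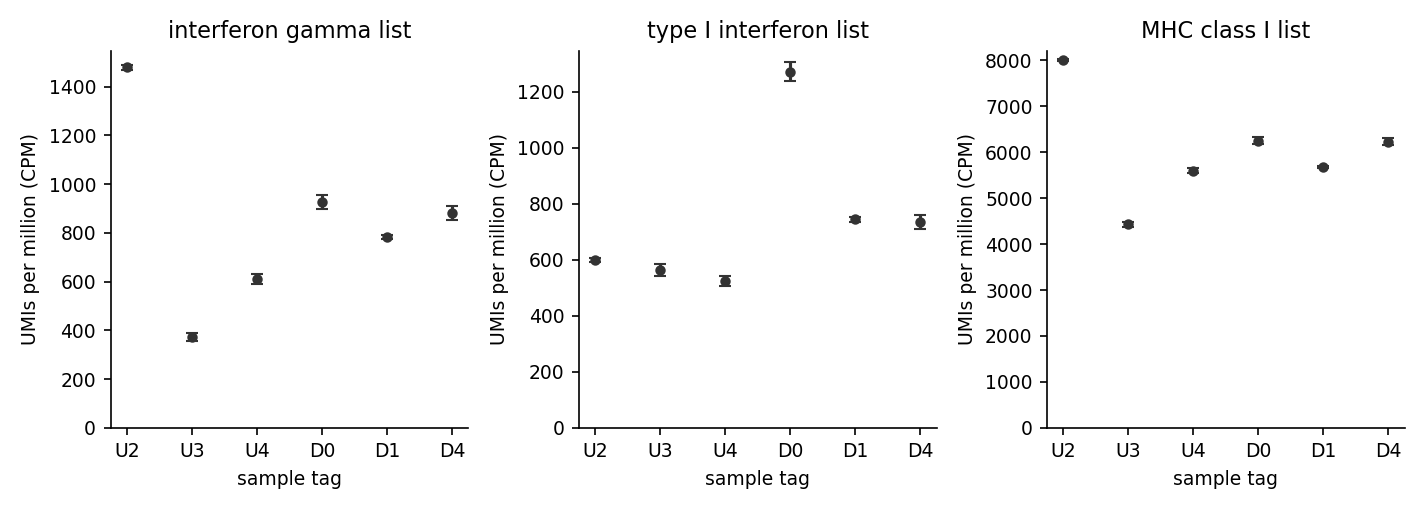
Summed interferon gamma and type I interferon lists (CPM) in Krt8-high cells of the 6 tagged samples, with exact 95% intervals. The interferon gamma list was highest in U2 (1480) and the type I list in D0 (1272).

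The 5 genes with the largest ratio between tagged samples in Krt8-high cells, of 9645 considered, were haemoglobin genes and a chemokine gene, and they rested on few cells. Hbb-bt (ENSMUSG00000073940) was 33.7 CPM (28.6 to 39.5) in U3 and 0.234 (0.00591 to 1.30, 1 UMI) in D0, Hbb-bs (ENSMUSG00000052305) 179 in U3 and 1.43 in D4, Hba-a1 (ENSMUSG00000069919) 34.8 in U3 and 0.478 in D4, and Hba-a2 (ENSMUSG00000069917) 26.1 in U3, 0.478 in D4 (2 UMIs) and 0 UMIs in D0, so which sample is lowest is open. Ccl4 (ENSMUSG00000018930), a chemokine of activated lymphocytes and macrophages, was 30.1 in D0 and had 0 UMIs in U4, where the limit of 3 counts was 61.5-fold lower. In U3 1 cell held 98.8% of the Hbb-bs UMIs, and in D0 1 cell held 72.9% of those of Ccl4. Hba-a1 and Hba-a2 are near-identical copies, as are parts of Hbb-bs and Hbb-bt, so how reads were split between them is uncertain. Without U3 the ratio of highest to lowest sample was 68.1 (11.2 to 2921) for Hbb-bt in place of 144, 62.7 (27.8 to 177) for Hbb-bs in place of 125 and 36.3 (9.26 to 324) for Hba-a1 in place of 72.9, and the highest Hba-a2 value was 13.9 CPM (D1). Other settings raised these ratios, up to 511 (83.8 to 22041) for Hbb-bt with doublets kept, 225 (98.1 to 647) for Hbb-bs with the stricter positive quantile, 162 (38.2 to 1565) for Hba-a1 with a minimum of 1000 genes and 182 (27.3 to 8561) for Ccl4 with 200 genes. Some lowered them, to 89.1 (51.0 to 163) for Hbb-bt with the stricter quantile and 35.5 (10.1 to 206) for Hba-a2 with mitochondrial UMIs under 10%.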

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

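The tests of lymphoid tissue, of untagged cells lost from U3 and of MHC class I across classes were written after the result was seen; the other tests below were written before their own values were seen, but after cell counts per class and tag had been. Values of the 6 tagged samples, which include both arms in unknown order, were put to Dixon's test at the 95% level. It marks about 1 group in 20 by chance, and 8 of 70 groups passed, 5 of them in U3. The groups are not independent, since class shares of a sample depend on one another and the same cells enter several groups. The count of 8 can therefore not be read as an excess over 1 in 20.

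T-like and B-like cells made up 55.4% (51.3 to 59.4) of the sample tagged U3 and 8.96% to 18.4% of the others, and with a minimum of 1000 genes 15% (9.85 to 21.5) of U3 and 2.92% to 6.65% of the others; T-like cells alone were 41.0% and B-like cells 14.3% of U3, both above the other 5. Loss of untagged cells from this sample is argued against as the whole cause, since with untagged cells given to their strongest tag the share was 36.5% (33.4 to 39.7) in U3 and 6.39% to 8.60% in the others, 4.24 times the highest of them. The placing by strongest tag was checked only on tagged cells, so this holds only as far as it places untagged cells rightly. Shallower cells throughout this sample are argued against too, as the median depth of its Krt8-high cells was 0.99 times the lowest of the others. Lymphoid tissue in the sample, such as a lymph node next to the tumour, cannot be told apart from other causes: in T-like cells the ratio of naive T genes (Lef1, Ccr7, Tcf7, Satb1, Il7r, Klf2, S1pr1) to cytotoxic genes was 2.74 in U3, 9.61 times that of the highest other sample, but the list was made after the clusters were seen and holds 3 of the 10 leading genes of the cluster with most T-like cells of U3. A treatment effect was not tested, because the arm of U3 is not known.

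The interferon gamma list in Krt8-high cells was highest in U2, though it did not pass Dixon's test. Selection by tag staining is argued against only under the assumption that untagged cells belong to their strongest tag, with which U2 was still 2.02 times the highest other sample. That placing was checked only on tagged cells. It left U2 with 1934 Krt8-high cells in place of 1821, so few untagged cells entered its value. A few cells are argued against as well, since the median Krt8-high cell of U2 was 1.77 times that of the highest other sample. Free RNA from macrophages is argued against, as Lyz2, C1qa, C1qb and C1qc together were 0.209 times the highest other sample in U2. A biological difference between these samples may stand behind it, as a hypothesis found on the same data, and treatment was not tested because the arm is not known.

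Of the cells without a tag, 90.3% were Krt8-high. Unnamed cells, of which 69.8% lacked a tag, were not part of the test across classes below. Whether lower depth is part of the cause cannot be told apart: untagged Krt8-high cells had 0.815 times (0.777 to 0.852) the median UMIs of tagged ones, an interval that crosses the bound set against the explanation, and among the deepest 25% of Krt8-high cells 23.1% (21 to 25.4) lacked a tag, 0.641 times the share in all of them, between the bounds set for and against it. Within Krt8-high cells, less MHC class I is a candidate explanation that the values go with: the list was 4101 CPM (4082 to 4119) in untagged Krt8-high cells, 0.926 times the lowest tagged sample, with H2-K1 at 418 against 1077 CPM and B2m at 2377 against 3462 in tagged cells. The tagged gene values are pooled, and 1821 of the 3719 tagged Krt8-high cells were of U2, which had the highest class I list (8002 CPM). These gene contrasts therefore also carry a difference between samples. As the only cause across classes, 2 of 7 classes went the other way beyond their intervals on pooled values, which met the bound set against it. Endothelial-like cells (35 cells) had 7543 CPM against 5934 in Krt8-high cells and 60.0% without a tag. B-like cells had 4735 CPM and 0 of 99 without a tag, but they were mostly of U3, where their list was 1.07 times the Krt8-high level. Their direction thus turned within that sample. Macrophage-like cells, which went with the explanation on pooled values, turned in most samples. Their list was lower than in Krt8-high cells in 3 of 5 samples (median ratio 0.930), though 0 of 487 lacked a tag. Within samples, then, B-like cells went with the explanation and macrophage-like cells mostly against it, beside the few endothelial-like cells. The bound against MHC class I as the only cause was met on pooled values, and the values within samples leave classes on both sides. The antibodies' targets are not given in the sources used here. The interferon gamma list was lower in untagged cells as well (437 against 1093 CPM, pooled with the same limit). Class I genes therefore need not be the ones that matter.

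NK-like cells were 9.07% of D0, above the other 5 samples. The median cell's own tag had 833 UMIs in U3 against 147 to 402 in the others. T-like and B-like cells, most of U3, had medians of 1083 and 870 tag UMIs and tagged Krt8-high cells 268. These class medians carry the U3 tag in part, since 252 of 770 T-like and 88 of 99 B-like cells were tagged U3. The U3 tag was also highest in cells of other tags, with a median of 41 UMIs against 1 to 18 for the other tags. The type I interferon list was 1272 CPM in the Krt8-high cells of D0 and 524 to 745 in the others. The same list was 2527 CPM in the macrophage-like cells of D0, the highest of 5 samples. The acetate list in macrophage-like cells was lowest in U3 among 5 samples, at 589 CPM (459 to 744, 24 cells), an interval that overlaps those of the other 4. The glycolysis list in T-like cells was lowest in U3, at 2230 CPM.

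Barcodes under the minimum of 500 genes, which entered values only under the alternative of 200 genes and there in part, held neutrophil genes at 13536 CPM (13245 to 13832) against 28.0 in the cells kept, led by S100a9 (6584 CPM) and S100a8 (5470 CPM). At least 3 UMIs of the list were seen in 75 of those 696 barcodes.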

How the results depend on the processing

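Tagged cells only, the sample U3 left out, the tag-call alternatives for classes and lists, the mixed-cell limits and the marker scores were chosen after the data were seen; the others were planned. The cause of the shifts below was not tested, except that a higher gene minimum removes shallow cells by construction. The share of cells with 1 tag was 63.6%, 67.8% with MULTIseqDemux and 59.1% with the stricter positive quantile. With a minimum of 200 genes, Krt8-high cells were 68.6% and T-like cells 10.5%. With 1000 genes they were 85.5% and 2.53%, Acss2 in T-like cells was 7.44 CPM, the interferon gamma ratio of highest to lowest sample was 3.18, and the T-like cell cycle list reversed to a log2 ratio of 1.05. At Leiden 0.5, Krt8-high cells were 76.0% and macrophage-like cells 6.78%. With doublets kept, Krt8-high cells were 75.2%. With tagged cells only, Krt8-high, macrophage-like and T-like cells were 67.2%, 8.21% and 13.9%. Without U3, Krt8-high and T-like cells were 77.1% and 7.06%, the interferon gamma ratio was 2.42, and the T-like interferon gamma, cell cycle and circadian clock lists reversed to log2 ratios of 0.13, 0.20 and 0.15. With mixed cells from 15%, T-like cells were 8.93%. The interferon gamma ratio was 3.32 with mitochondrial UMIs under 25% and 3.25 with the stricter quantile. Acss2 in Krt8-high cells and Acss1 in macrophage-like cells stayed within their intervals under all 16 alternatives. Some of these left the value exactly as it was: both mixed-cell limits and the marker score of 0.5 for Acss2, and both marker scores for Acss1. An alternative that changed nothing counts as staying within the interval, here and in the counts below.

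Of 808 class shares under an alternative 713 stayed within their interval and 95 moved, of 336 sample ratios 306 and 30, of 1326 list ratios 1177 and 145 with 4 reversed, of 5040 gene values 4658 and 382, and of 14 tag counts 8 and 6. The point values of 24 list ratios took the other sign. Whether or not they left their interval, 57 class shares, 23 sample ratios and 74 gene values changed by over 1.5 times. No paired comparison of arms was possible because no arm is known. Not run, because no arm is given for a tag, were the comparison of ACSS2i with vehicle and its alternatives (DESeq2, size factors, no filter, each replicate left out, a replicate block, and the estimated correlation). Low counts limit several gene values, among them Acss2 and Acss1, with 23 and 12 UMIs in T-like cells.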

Other observations

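The genes singled out here were chosen after their values were seen. Single genes differed between the Krt8-high cells and the immune classes, in both directions. Trp53 was 4.99 CPM (4.63 to 5.36) in Krt8-high cells, 58.0 (48.0 to 69.5) in macrophage-like and 88.6 (73.7 to 105) in T-like cells, and higher than in the Krt8-high cells in 5 of 5 and 6 of 6 tagged samples. Cdkn2a, a locus that encodes cell cycle inhibitors, was 354 CPM in Krt8-high, 12.8 in macrophage-like and 45.4 in T-like cells. The heat shock gene Hspa1a, which shares reads with Hspa1b, was 3.00 CPM in Krt8-high and 198 in T-like cells. The epithelial adhesion gene Epcam had 1 UMI among all Krt8-high cells, while Sox9 and Hmga2 were at 765 and 534 CPM. The lactate exporter gene Slc16a3 had 22 UMIs (0.147 CPM) in Krt8-high cells and was higher in macrophage-like cells in 5 of 5 samples.

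NK-like cells carried granzyme transcripts at high levels. Gzmc was 14594 CPM in NK-like cells against 233 in T-like cells, and Gzmb, Gzma and Prf1 were 2393, 1932 and 737 CPM in NK-like cells. Of 10 fatty acid oxidation genes 3 were higher and 1 lower than in Krt8-high cells (list ratio 1.46, higher in 3 of 3 samples), and of 14 glycolysis genes 12 were lower (0.358). Dendritic-like cells had all 7 MHC class II genes higher (list ratio 1802) and 8 of 17 cholesterol synthesis genes lower (0.546), with 1 sample of enough cells.

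In Krt8-high cells without the 1% of cells of each sample that held most of a gene, the largest ratios between tagged samples were those of Cxcl9, a chemokine induced by interferon gamma (17.4 CPM in U2, 0.218 from 1 UMI in U3), Saa3 (13.1 in U2, 0.490 from 3 UMIs in U4), F13a1 (13.9 in D4, 0.654 in U4), Gm4841 (13.4 in U2, 0.653 in U3) and Matn4 (14.3 in D4, 0.701 in D0). In T-like cells Ifng was 453 CPM in U2, 245 in D1, 175 in D4, 111 in U4, 104 in D0 and 20.3 in U3.

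Median tag UMIs per cell were 1083 in T-like, 838 in macrophage-like, 268 in tagged Krt8-high, 162 in endothelial-like, 144.5 in fibroblast-like and 120.0 in untagged Krt8-high cells. T, B and NK genes were present in mice whose strain is written as NGS in the labels.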
